A study of Mus musculus with 10 samples.

How the data were processed

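RNA of forelimb-bud ectoderm from mouse (Mus musculus) embryos was measured by RNA sequencing. Per the labels' protocols, the ectoderm was peeled with forceps after 20 min in 0.25% trypsin on ice, and each replicate took about 2 forelimb buds. Libraries were made with a full-length SMART-Seq v4 kit and Nextera XT tagmentation, per the labels' protocols. That chemistry does not mark the strand of a transcript and carries no molecular identifiers, so reads of overlapping genes on opposite strands cannot be told apart and PCR copies are counted as reads. Floors for counts of 0 therefore cover counting error only.

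The labels describe 10 RNA samples in 4 groups. At embryonic day 9.75 (E9.75) these are 3 samples labelled as lacking both Sp8 and Sp6 (double knockout, DKO) and 3 wild-type (WT) littermates. At E10.5 they are 2 samples lacking Sp6 and 2 WT littermates. The table used here is that of the DKO comparison and has 6 columns, 3 named DKO and 3 named WT, which were taken as the E9.75 groups. The E10.5 libraries, the chromatin immunoprecipitation named in the series design and any Sp8 single knockout were not analysed here. The columns carry numbers that match no replicate number of the labels, so a column stands for a replicate of its group without a replicate number. The libraries are named by group and column number: DKO 17, DKO 40, DKO 41, WT 32, WT 53 and WT 56. Littermates are named in the labels, but not which samples came from which embryo or litter, so p-values measure the spread between these samples.

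The authors deposited raw whole-number counts per gene for 55401 genes. Per the submitters' processing notes, FastQC, fastp, HISAT2, Cufflinks, StringTie and DESeq2 were used with the builds GRCm38 and mm10; their versions, their roles and the step that wrote the counts are not given in the sources used here. Values of 1 outnumbered values of 2 in each library, for example 1490 against 617 genes in DKO 17, so low counts may be rounded estimates. Gene symbols came from the deposited row names. Positions and biotypes came from the GENCODE M21 annotation of GRCm38, matched by Ensembl identifier without its version: 55141 of 55401 identifiers (99.53%) matched. In 110 rows the symbol repeated that of an earlier row. The edgeR test kept each identifier, and for the gene lists the row of a symbol with the highest mean count was used. Exon overlaps between genes were taken from the same annotation. Besides the overlaps given with the results, exons of Pdgfra, Meis1, Cdkn1a, Jun and Ndrg1 overlap those of other genes by 652, 1925, 273, 232 and 556 bases.

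Library totals were 85560785 counts in DKO 17, 75996667 in DKO 40, 86142321 in DKO 41, 86737555 in WT 32, 64432348 in WT 53 and 87040786 in WT 56. A gene with 0 counts in the DKO group was given a floor of 3 counts over the group, or 0.012 CPM, and a fold against it is stated as a lower bound. The same floor over the WT group is 0.0127 CPM. Where a group was at 0 counts only with 1 library left out, the floor was 3 counts over its libraries left. Each pair of libraries was compared by a chi-square test over genes, and each pair differed by more than sampling noise. Separate libraries of 1 sample could differ as much with this chemistry, so the 6 libraries were taken as separate samples from the labels, not from this test.

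Levels are counts-per-million values (CPM) scaled by TMM, given as mean ± SD over the 3 libraries of a group. Changes were tested with edgeR 4.0.16 (filterByExpr, TMM, glmQLFit with robust estimation and legacy=FALSE, quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment over the 19126 genes left by the filter. A gene was called at an adjusted p under 0.05. Log2 fold changes are DKO minus WT. The standard error (SE) is the size of the log2 fold change divided by the square root of F, and is not given where a group is at 0 counts. The 24 gene lists were tested with camera in limma 3.58.1, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 23 lists with 3 or more tested genes; the macrophage list had 2. Each list test is set beside the same test with an estimated correlation. Principal components were taken from log2 CPM with a prior count of 2.

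The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined, with 1 exception. The fixed plan listed legacy=TRUE of glmQLFit as an alternative but did not name the setting of the main test, and legacy=FALSE, which is not the default of this edgeR version, was taken after a first run on the data with the default. The default calls 546 genes in place of 863. The rule names Sp8, Sp6, Fgf8, En1, Wnt7a, Bmp4, Dlx5, Sp9 and Msx2 always. It adds the 12 largest rises and the 12 largest falls by log2 fold change among called genes with a mean of 5 CPM or more in the higher group and no overlap between the libraries of the groups, leaving out predicted genes, pseudogenes and sex-linked genes. It adds the 4 members of each list with the smallest p, and a further gene only where a small count or a test singles it out, said to be chosen after its values were seen. The rule named 117 genes, of which 84 were called; the values of some of them are not reported here.

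The alternatives tried were DESeq2 1.42.0 and limma-voom in place of edgeR, size factors of DESeq2 or library totals in place of TMM, no filter or a stricter filter (5 CPM in 3 libraries), non-robust and legacy dispersion estimates, a test against a 1.5-fold change, an estimated correlation or fry for the lists, and leaving out each library in turn. The planned block on replicate number was not run, because the columns carry no replicate number. Chosen after seeing the data were the sex of the embryo as a covariate, and leaving out WT 32 and DKO 41 together. Sex was read from Xist and the Y-linked genes: DKO 40 and WT 53 held Xist counts and 0 counts of Ddx3y, Kdm5d, Uty and Eif2s3y, and the other 4 libraries held counts of each Y-linked gene and at most 62 counts of Xist. The steps were tested on simulated data drawn from the means and depths of these libraries. The changed genes were drawn from those above a minimum mean level, so the shares recovered do not cover the lowest genes. For this comparison, edgeR recovered 46% of 100 genes changed 2-fold and 79% of 100 genes changed 4-fold among 18253 genes, and 6.7% of its calls were false. DESeq2, run on 19126 genes, recovered 64% and 86% with 33.3% false calls, and voom, run on 18253 genes, 40% and 77% with 4.1% false calls. The shares of false calls depend on the number of changed genes and do not carry over to the real table. Camera called the simulated changed list and 0 of 20 unchanged lists. The simulated genes were drawn independently, so this cannot show how camera behaves with the preset correlation where the genes of a list move together. The correlations estimated for the real lists ran from -0.158 (endothelial) to 0.938 (erythroid). Python 3.11.15 scripts with scipy ran the tests on single values.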

Results

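Gene expression was measured by RNA sequencing in the ectoderm of mouse forelimb buds, the epithelial sheet whose distal rim thickens into the apical ectodermal ridge. At E9.75, 3 libraries came from embryos labelled as double knockouts (DKO) of the zinc finger transcription factors Sp8 and Sp6, and 3 from WT littermates. The library totals ranged from 64432348 to 87040786 counts, and between 21716 and 24651 genes had a count. On the first principal component, which held 38.1% of the variance, the 3 DKO libraries scored between -80.6 and -50.4. The 3 WT libraries scored between 41.7 and 100.7. The mean correlation of log2 CPM was 0.954 within WT, 0.953 within DKO and 0.932 between the groups. On the second component (25.7%), WT 53 scored 86.3 and the other WT libraries -61.1 and -55.1. DKO 17, DKO 40 and DKO 41 scored 56.3, 16.1 and -42.5 there. The highest scores were those of WT 53 and DKO 17, which had the fewest genes with a count (21716 and 22798). A further 4 libraries at E10.5, from embryos lacking Sp6 and their WT littermates, were not analysed here.

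**Figure D1:**
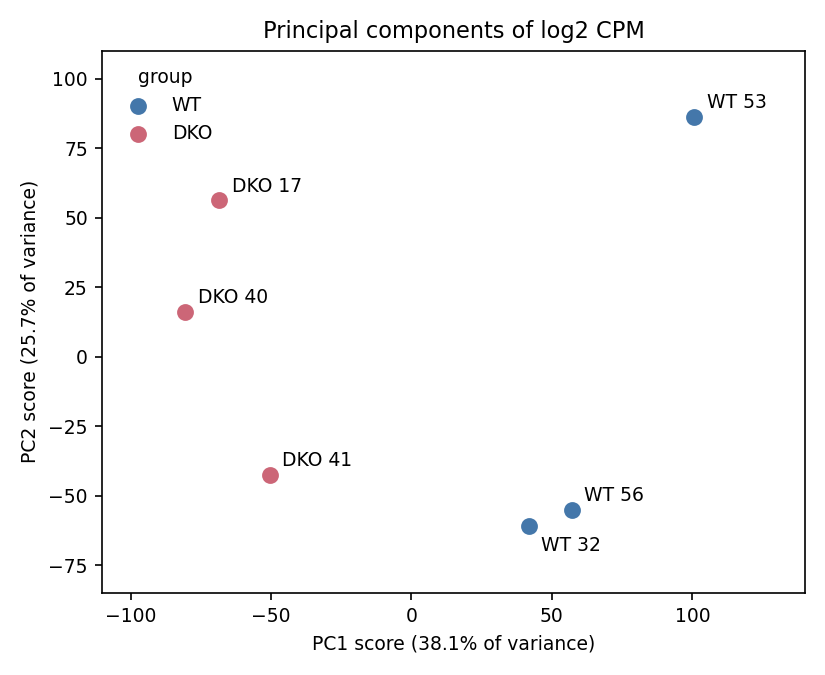
Each point is a library, placed by its scores on the first (x axis, 38.1% of variance) and second (y axis, 25.7%) principal components of centred log2 CPM, which have no unit. The DKO libraries lie between -80.6 and -50.4 on the first component and the WT libraries between 41.7 and 100.7.

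The comparison asks which genes of the limb ectoderm differ in level between DKO and WT. Each library pooled the RNA of the peeled tissue. It cannot tell less RNA per cell from fewer cells of a kind, such as ridge cells. Of the targeted genes themselves, Sp8 (ENSMUSG00000048562.7, GRCm38 chromosome 12, 118846329 to 118852576) fell from 36.2 ± 6.22 CPM in WT to 3.68 ± 1.90 CPM in DKO (SD, n = 3 each), a 9.84-fold decrease. Its log2 fold change was -3.29 (SE 0.302; edgeR adjusted p = 0.000806), with 5.86, 2.38 and 2.80 CPM in DKO 17, DKO 40 and DKO 41. Sp6 (ENSMUSG00000038560.7, chromosome 11, 97013394 to 97024734) was at 286.8 ± 50.65 CPM in WT and 74.68 ± 59.67 CPM in DKO, with 133.2 CPM in DKO 17, 13.9 in DKO 40 and 76.9 in DKO 41. Each DKO library was below each WT library, but the log2 fold change of -1.94 (SE 0.682) did not pass the threshold (edgeR adjusted p = 0.207). Without DKO 40 it passed, at -1.45 (edgeR adjusted p = 0.0487), and without DKO 17 it was -2.64 and did not pass (adjusted p = 0.126). The counts are totals per gene and do not show which part of Sp6 they came from, and 3329 bases of its exons overlap those of the antisense gene Gm11532, which this chemistry cannot separate.

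Of 19 markers of the apical ectodermal ridge tested, 12 fell in DKO and 0 rose. Without DKO 41, 13 were called lower and 1 higher, and without any other single library 10 or 11 lower and 0 higher. Fgf8, the growth factor that marks the ridge and sustains limb outgrowth (ENSMUSG00000025219.13, chromosome 19, 45736798 to 45742915), dropped from 1259 ± 111.6 CPM in WT to 4.91 ± 7.48 CPM in DKO, 256-fold lower. Its log2 fold change was -7.99 (SE 0.916, edgeR adjusted p = 0.00954). DKO 17 kept 13.5 CPM of Fgf8, against 0.261 in DKO 40 and 0.930 in DKO 41, and without DKO 17 the log2 fold change was -10.98. Fgf4 (ENSMUSG00000050917.5, chromosome 7, 144847367 to 144865243), the partner signal of Fgf8 in the ridge, had 0 counts in the DKO libraries and 39.7 ± 29.3 CPM in WT. That is at least 3293-fold lower (adjusted p = 0.0312), or at least 2190-fold, 2110-fold and 2010-fold without DKO 17, DKO 41 and WT 56. The WNT agonist Rspo2 was 109-fold lower (76.3 ± 18.7 to 0.700 ± 0.453 CPM), the hyaluronan receptor Cd44 was 20.7-fold lower and the related SP factor Sp9 was 11.0-fold lower. Wnt5a fell from 275 ± 25.1 to 34.2 ± 17.6 CPM, Bmp4 from 253.1 ± 42.48 to 51.7 ± 16.66 CPM and the homeobox gene Dlx1 from 110.6 ± 21.85 to 22.6 ± 4.75 CPM. The log2 fold change of Cd44 was -4.37, and -5.49 without DKO 17, and that of Rspo2 was -6.73, and -7.34 without DKO 41. The exons of Dlx1, Wnt5a, Sp9 and Bmp4 overlap those of other genes by 335, 358, 270 and 89 bases.

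The other 7 ridge markers did not pass the threshold. The median log2 fold change of the 19 was -1.74, the same with Fgf4 at its bound. Adjusted over the list alone, 14 were lower. The list moved down relative to other genes (camera adjusted p = 4.86e-31; adjusted p = 0.12 with an estimated correlation). Dlx5 was at 51.6 ± 8.58 CPM in WT and 56.3 ± 21.6 in DKO (adjusted p = 0.859), and Msx2 at 245.8 ± 75.98 and 193.4 ± 46.67 CPM (adjusted p = 0.503). Among the genes that set dorsal and ventral limb fates, the ventral gene En1 fell 3.20-fold (18.1 ± 6.73 to 5.66 ± 2.63 CPM, adjusted p = 0.0454). The dorsal signal Wnt7a was at 138 ± 25.3 CPM in WT and 60.8 ± 48.5 CPM in DKO (adjusted p = 0.273), with 116.3 CPM in DKO 17, and its target Lmx1b at 15.8 ± 7.88 and 19.2 ± 6.09 CPM. The list of these 3 genes was not called (camera adjusted p = 0.102, 0.00169 without DKO 17; 1 of 3 lower, also adjusted over the list alone). Leaving out 1 library changed some of these calls. Fgf4 was lost without DKO 17 or WT 32 (adjusted p = 0.0594 and 0.0726) and En1 without any 1 of the 6 libraries (adjusted p between 0.0536 and 0.144). Wnt7a passed without DKO 17 (log2 fold change -2.06, adjusted p = 0.0039).

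**Figure D2:**
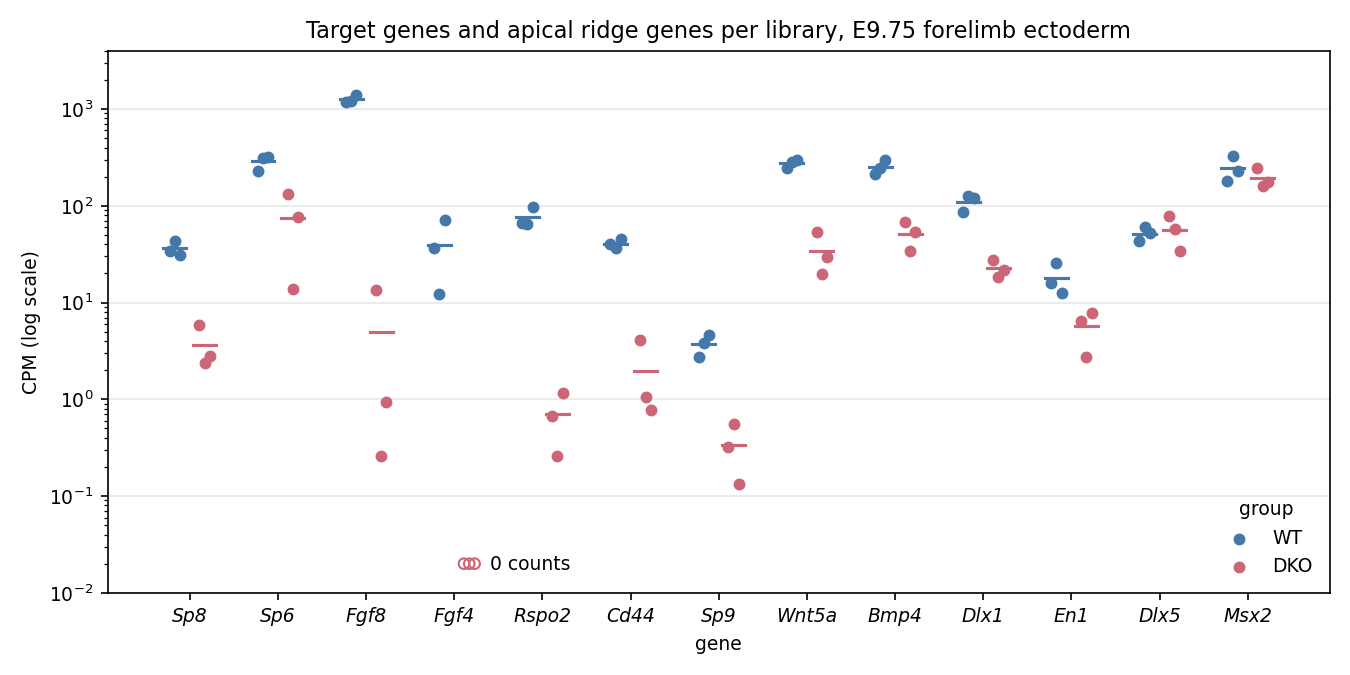
CPM on a log axis (y) of the targeted genes and of ridge and limb-patterning genes (x) in each library; filled points are single libraries, bars are means over the 3 libraries of a group, and open circles mark 0 counts, drawn at the foot of the axis. WT Fgf8 lies between 1181 and 1387 CPM and DKO Fgf8 between 0.261 and 13.5 CPM, while Dlx5 and Msx2 overlap between the groups.

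Across the transcriptome, 863 of 19126 genes tested (4.51%) changed, 325 higher and 538 lower in DKO. Over a 2-fold change there were 249 higher and 424 lower. In 862 of the 863, each DKO library lay on the same side of each WT library. With so few libraries a call makes this likely, so it adds no support of its own. Over the tested genes the groups were separate in this way for 4191 (21.9%). Chance gives 10% for a single gene, but genes move together and the spread of this share was not measured. Without DKO 40, WT 32, WT 53 or WT 56 the count was 295, 313, 534 and 247, and 210 calls (41 higher, 169 lower) were kept whichever of the 6 libraries was left out. WT 32 held markers of limb mesenchyme (Prrx1, chosen after its values were seen, 29.0 CPM against 1.61 and 0.412 in the other WT libraries), and DKO 41 held the most globin transcript. Without both of these libraries 377 genes were called, 95 higher and 282 lower.

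Besides Fgf4, Fgf8 and Rspo2, the largest falls were in genes at or near 0 counts in DKO. Vwde, which encodes a secreted protein with von Willebrand factor D and EGF domains, fell from 23.2 ± 3.44 CPM to 0 counts (at least 1925-fold lower). So did the calcium-activated chloride channel regulator Clca1 (14.6 ± 4.87 CPM, at least 1210-fold) and the aldehyde oxidase Aox3 (5.13 ± 2.99 CPM, at least 426-fold). Without DKO 17 and DKO 41 these bounds were 1280-fold and 1240-fold for Vwde, 805-fold and 776-fold for Clca1, and 284-fold and 273-fold for Aox3. The homeobox gene Nkx1-1 fell 637-fold from 25.5 ± 3.20 CPM (log2 fold change -9.25, SE 0.510, adjusted p = 1.71e-05). Slc35d3, Sowaha and Sp7, another SP factor best known from bone formation, were 456-fold, 277-fold and 263-fold lower from 11.9, 9.31 and 6.88 CPM. Tent5a, a poly(A) polymerase gene, dropped from 79.1 ± 12.5 to 0.354 ± 0.115 CPM (log2 fold change -7.82, SE 0.288, adjusted p = 7.72e-06), and the sphingomyelinase gene Smpd3 from 33.5 ± 20.1 to 0.218 ± 0.0669 CPM. Of these genes, the call of Aox3 was lost without DKO 40, WT 32 or WT 56 (adjusted p between 0.0656 and 0.0862). For 4 of these genes the DKO counts came from 1 library, and without it the DKO group was at 0 counts: Nkx1-1 was then at least 1410-fold lower (without DKO 17), Sp7 at least 396-fold (without DKO 40), and Sowaha and Slc35d3 at least 496-fold and 636-fold (without DKO 41). The smallest falls of these 4 genes with 1 library left out were log2 fold changes of -8.64 for Nkx1-1 (from -9.25) and -7.47 for Sp7 (from -8.08). They were -7.38 for Sowaha (from -7.95) and -8.09 for Slc35d3 (from -8.65). The exons of Sowaha and Smpd3 overlap other genes by 109 and 247 bases.

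The largest rises began from low levels in WT. Hand1, a basic helix-loop-helix factor of heart, placenta and flank mesoderm, rose from 0.0926 ± 0.161 to 7.18 ± 2.38 CPM (77.5-fold; log2 fold change 6.12, SE 0.710, adjusted p = 0.000772). Its WT counts were in WT 32 alone, and without that library it was at least 361-fold higher. The lowest log2 fold change of Hand1 with 1 library left out was 5.46. The receptor tyrosine kinase gene Ret rose from 0.403 ± 0.285 to 27.2 ± 18.8 CPM (67.5-fold). Starting levels were higher for the T-box co-repressor gene Ripply3, which rose 8.82-fold to 64.6 ± 24.6 CPM. The myelin protein gene Pmp22 rose 8.05-fold to 47.2 ± 6.78 CPM, and the paternally expressed gene Peg10 rose 7.77-fold to 151 ± 58.1 CPM. Also among the 12 largest rises were Plet1 (44.9-fold), Crispld2 (42.6-fold), Car4 (15.9-fold), Hoxd1 (13.1-fold), Cpm (10.3-fold), Tac2 (8.28-fold) and Sh2d3c (7.95-fold). The calls of these 7 genes, unlike those of Hand1, Ret, Ripply3, Pmp22 and Peg10, were lost when some single libraries were left out. This held for Cpm without WT 56 (adjusted p = 0.0687) and for Car4 and Hoxd1 without DKO 40, WT 32 or WT 56 (up to 0.0915). Plet1 was lost without any but DKO 41 (up to 0.134), and Crispld2, Sh2d3c and Tac2 without any but DKO 17 (up to 0.166). Their log2 fold changes moved too: without DKO 40 to 5.31 for Ret, 4.84 for Plet1 and 2.69 for Cpm (from 5.99, 5.47 and 3.31), without WT 32 to 6.75 for Ret and 3.61 for Tac2 (from 2.92), and without WT 53 to 4.78 for Car4 and 5.19 for Hoxd1 (from 4.09 and 3.89). The exons of Plet1 and Sh2d3c overlap other genes by 261 and 174 bases.

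Signalling genes changed in several pathways. The lists share genes, so their results are not independent of each other or of the ridge list. Among the genes called lower, Rspo2, Bmp4, Bmp7 and Sp9 are also ridge markers, and Bambi is on both the WNT and the BMP list. In the NOTCH list, 5 of 12 tested genes were lower and 0 higher (7 lower adjusted over the list alone). Its response gene Heyl fell 8.87-fold (38.2 ± 10.8 to 4.30 ± 2.62 CPM, adjusted p = 0.00287), its feedback gene Nrarp 4.06-fold, the ligand Dll1 3.59-fold and Hes1 1.95-fold. The list test gave an adjusted p of 8.78e-08 (camera; adjusted p = 0.401 with an estimated correlation), and the count of lower genes was 2, 1 and 2 without DKO 40, WT 32 and WT 56. In the hedgehog list, the response genes Gli1 (5.15-fold) and Ptch1 (2.99-fold) fell while the co-receptor gene Cdon rose 3.41-fold. With 3 of 8 lower and 1 higher (3 and 3 adjusted over the list alone), the list was not called (adjusted p = 0.622). Of 24 WNT genes, 3 were lower (Rspo2, Bambi and Kremen1) and the feedback inhibitor Nkd1 was higher, rising 2.13-fold. Adjusted over the list alone, 6 were lower and 4 higher (camera adjusted p = 0.00177, adjusted p = 0.401 with an estimated correlation). Of 19 BMP genes, Bmp4, Bmp7, Bambi and Smad6 were lower and 0 were higher (5 and 3 adjusted over the list alone; camera adjusted p = 0.0808, and between 0.00098 and 0.0467 without DKO 17, WT 32 or WT 56). Bambi, a decoy receptor, fell from 666 ± 108 to 161 ± 75.5 CPM.

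Of 14 FGF feedback genes, 2 were lower and 0 higher (3 and 1 adjusted over the list alone; camera adjusted p = 0.132, and 8.49e-05 without DKO 17). Spry1 fell 4.60-fold from 417 ± 88.9 CPM and Dusp6 1.71-fold from 157 ± 28.4 CPM. In the retinoic acid list, 3 of 13 genes rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.119, and 0.035 without WT 32). Cyp26a1, which degrades retinoic acid, fell 15.8-fold (45.9 ± 5.01 to 2.91 ± 2.31 CPM, adjusted p = 0.00165). The retinoic acid receptor gene Rarb rose 4.53-fold (1.75 ± 0.519 to 7.92 ± 3.35 CPM) and Crabp2, which carries retinoic acid in the cell, rose 2.32-fold. Aldh1a2, which makes retinoic acid, had 0 counts in WT and 0.641 ± 0.224 CPM in DKO, at least 50.7-fold higher (adjusted p = 0.0325), or at least 32.2-fold and 32-fold without WT 32 and WT 56. In the family of SP and KLF factors, 4 of 21 genes were lower and 0 higher (5 lower adjusted over the list alone): Sp7, Sp9, Klf13 (1.88-fold) and Klf10 (1.64-fold). The camera adjusted p was 6.55e-06 (adjusted p = 0.12 with an estimated correlation).

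Not every one of these signalling calls held with 1 library fewer. Heyl, Rspo2, Bambi, Bmp4, Cyp26a1, Sp7 and Sp9 kept theirs. Nrarp was lost without DKO 40 or WT 32 (adjusted p up to 0.0704), Bmp7 without DKO 40 or WT 56 (0.0639), Crabp2 without DKO 40 or WT 53 (0.105) and Cdon without WT 32 or WT 56 (0.0688). So were Dll1, Gli1, Ptch1 and Klf13 without DKO 40, WT 32 or WT 56 (up to 0.102). Hes1 was lost without any 1 WT library (0.0872), Nkd1 and Kremen1 without DKO 40 or any 1 WT library (up to 0.129), and Dusp6 without DKO 40, DKO 41, WT 32 or WT 53 (0.135). Rarb and Spry1 were lost without any but DKO 17 (up to 0.148), Klf10 without any but DKO 41 (0.121), and Smad6 and Aldh1a2 without any 1 of the 6 (up to 0.145). Of the WNT genes, 2 were lower without DKO 40 or any 1 WT library, 4 without DKO 17 and 6 without DKO 41. The counts of lower genes were 2 without DKO 40 or WT 56 for BMP, and 1 without DKO 40, WT 32 or WT 56 for hedgehog. They were 2 without DKO 40, WT 32 or WT 56 for the SP and KLF family, and for FGF feedback 4 without DKO 17, 0 without DKO 40 or WT 32 and 1 without the others. In the retinoic acid list, without any 1 library but DKO 17, 1 gene was lower and at most 1 higher. Without DKO 41, 3 BMP genes were called higher, and the log2 fold changes of Heyl and Gli1 were -3.78 and -3.19 (from -3.13 and -2.32); that of Spry1 was -2.89 without DKO 17 (from -2.20). The exons of Rarb overlap Top2b, those of Gli1 a predicted gene, and those of Nrarp, Spry1 and Dll1 overlap predicted or unnamed transcripts by 710 bases or more.

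Of 27 genes of embryonic ectoderm and epithelium, 7 were lower and 0 higher (16 lower adjusted over the list alone; camera adjusted p = 1.32e-09, adjusted p = 0.401 with an estimated correlation). The desmosome gene Pkp1 fell 33.6-fold (9.99 ± 2.09 to 0.297 ± 0.283 CPM, adjusted p = 0.000757), Dsc3 6.22-fold, Perp 1.96-fold (534 ± 45.6 to 273 ± 84.2 CPM) and Epcam 1.45-fold (610 ± 36.0 to 420 ± 31.7 CPM). The count of lower genes was 1 without DKO 40, WT 32 or WT 56, 3 without DKO 17 and 11 without DKO 41. The log2 fold change of Pkp1 was -5.06, and -6.11 without DKO 17. The calls of Dsc3, Perp and Epcam were lost without DKO 40 or any 1 WT library (up to 0.141), those of Dsc3 and Perp also without DKO 17. In the periderm list the simple-epithelium keratin Krt19 rose 2.70-fold (152 ± 11.8 to 409 ± 117 CPM, adjusted p = 0.00596), while Krt17 and Sfn fell, with log2 fold changes of -1.89 and -0.72. In all, 4 of its 12 genes were lower and 2 higher (6 and 2 adjusted over the list alone), with a camera adjusted p of 0.00251, 0.127 without DKO 40 and 0.519 with an estimated correlation. The calls of Sfn and Krt17 were lost without DKO 17, DKO 40, WT 32 or WT 56 (up to 0.12). The count of lower periderm genes was 0 without DKO 40, WT 32 or WT 56 and 1 without DKO 17, and 1 was higher without any 1 library but DKO 17.

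Basement membrane genes moved both ways. The type IV collagen genes Col4a6 and Col4a5, neighbours on the X chromosome, rose 5.77-fold (11.1 ± 3.07 to 64.1 ± 12.6 CPM) and 3.15-fold, while the hemidesmosome integrin Itgb4 fell 3.99-fold and Frem1, a basement membrane protein of the embryonic epidermis, 4.45-fold. These 4 calls held whichever library was left out. Of 24 genes on the list, 3 were higher and 5 lower (4 and 9 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0612; 0.00225 to 0.0388 without DKO 40, DKO 41 or WT 53). The count of lower genes was 3 without DKO 40 and 2 without WT 32 or WT 56. The exons of Itgb4 overlap another gene by 537 bases.

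Markers of other cell types differed between single libraries. Of 25 limb mesenchyme markers, Meis2 (2.07-fold) and Meis1 (1.55-fold) rose, while Pdgfra fell 8.69-fold and Vim 2.35-fold. Adjusted over the list alone, 9 were higher and 5 lower, and the camera adjusted p was 0.119 (0.0413 and 1.94e-05 without DKO 17 or WT 32). The count of higher genes was 5 without DKO 17 and 1 without DKO 40, WT 53 or WT 56. Prrx1 was at 3.51, 23.3 and 12.8 CPM in DKO 17, DKO 40 and DKO 41. Erythroid genes summed to 27.5, 128 and 918 CPM in DKO 17, DKO 40 and DKO 41 and to 0.591, 302 and 0.710 CPM in WT 32, WT 53 and WT 56. The erythroid list was called up (camera adjusted p = 0.0183, 0.146 without DKO 41, 0.555 with an estimated correlation). Of its 9 genes 0 were called by edgeR, also adjusted over the list alone, and 0 by DESeq2 or voom. At an unadjusted p under 0.05 there were 2, Hbb-bs (0.0199) and Hbb-bt (0.0296), and both passed without DKO 17 (adjusted p = 0.0218 and 0.0449). The endothelial list (adjusted p = 0.304) had 0 of 6 genes called by edgeR, DESeq2 or voom and 1 at an unadjusted p under 0.05, Egfl7, at 38.7 ± 7.61 and 58.7 ± 13.2 CPM. In the macrophage list 0 of 2 genes were called by any of these tools or at an unadjusted p under 0.05, with C1qb and Fcer1g under 1 CPM.

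Of 8 neural and neural crest genes, Tubb3 fell 41.2-fold (91.3 ± 22.5 to 2.22 ± 1.49 CPM, adjusted p = 0.000182) and Sox2 17.1-fold from 1.34 ± 0.580 CPM, while Stmn2 rose from 3 to 249 counts over the group (88.9-fold in CPM, 95% counting interval 26.7 to 386). The list was not called (camera adjusted p = 0.235; 2 higher and 2 lower adjusted over the list alone). Of 7 muscle and somite genes, Meox1 fell 4.08-fold (67.4 ± 14.0 to 16.5 ± 7.02 CPM). In that list 1 was lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.743, and 0.0413 without DKO 17). Tubb3, Meox1, Meis2, Vim and Pdgfra kept their calls whichever library was left out. The log2 fold change of Tubb3 was -5.33, and -6.08 without DKO 41, and that of Sox2 was -4.09, and -4.99 without DKO 17. Sox2 was lost without DKO 40 or WT 56 (adjusted p up to 0.0676), Meis1 without DKO 40 or any 1 WT library (0.152) and Stmn2 without any but DKO 41 (0.118). The WT counts of Stmn2 were in WT 56 alone, and without that library it was at least 50.8-fold higher. The lowest log2 fold change of Stmn2 with 1 library left out was 5.52 (from 6.14).

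Of 26 cell cycle genes, 0 were called by edgeR (also adjusted over the list alone), DESeq2 or voom, and 3 had an unadjusted p under 0.05. Without DKO 17, 1 was called lower. Mki67 was at 111 ± 21.5 CPM in WT and 141 ± 1.07 CPM in DKO (adjusted p = 0.256), and Mcm3 at 580 ± 45.9 and 477 ± 28.0 CPM (adjusted p = 0.186). The camera test gave an adjusted p of 0.933. Of 18 p53 target and cell death genes, 4 were lower and 1 higher (6 and 1 adjusted over the list alone; camera adjusted p = 0.00174, adjusted p = 0.401 with an estimated correlation). The cell cycle inhibitor Cdkn1a fell 2.22-fold (162 ± 23.6 to 72.6 ± 17.2 CPM), Sesn1 2.36-fold and Plk2 1.95-fold, while the pro-apoptotic gene Bbc3 rose 2.04-fold (8.76 ± 1.85 to 17.9 ± 3.43 CPM). Plk2 kept its call whichever library was left out. Sesn1 was lost without DKO 40 (adjusted p = 0.0571), Cdkn1a without DKO 40 or WT 56 (up to 0.068) and Bbc3 without DKO 40, DKO 41, WT 32 or WT 56 (up to 0.193). The count of lower genes was 1 without DKO 40 and 2 without WT 56.

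Of 18 immediate early and dissociation stress genes, Nr4a1 (2.53-fold), Jun (1.82-fold) and Socs3 (1.79-fold) fell and 0 rose (6 and 1 adjusted over the list alone). Atf3 was at 1.83 ± 0.386 CPM in WT and 6.42 ± 3.72 CPM in DKO (adjusted p = 0.0755), and without DKO 41 it was the 1 gene called higher (0.0326). The camera adjusted p was 0.0277, between 0.109 and 0.178 without DKO 40, DKO 41 or WT 53, and 0.519 with an estimated correlation. Of 17 hypoxia and glycolysis genes, P4ha1 (2.04-fold), Ndrg1 (2.71-fold) and Vegfa (1.87-fold) fell and Mif rose 1.52-fold, from 985 ± 116 to 1498 ± 203.7 CPM. The list was not called (4 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.119, and 0.0297 without WT 32). Of these genes P4ha1 kept its call whichever library was left out. Ndrg1 was lost without DKO 40 (adjusted p = 0.0508) and Nr4a1 without DKO 40 or WT 32 (0.0611). The same was so for Jun and Mif without DKO 17, DKO 40, WT 32 or WT 56 (up to 0.191), Vegfa without any but WT 53 (0.148) and Socs3 without any 1 of the 6 (0.166). The count of lower stress genes was 0 without DKO 40 or WT 32 and 1 without DKO 17 or WT 56, and that of hypoxia genes 1 without DKO 40. The 13 mitochondrial transcripts held 0 calls by edgeR, DESeq2 or voom and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.563, and 0.0103 without DKO 41). Among them mt-Nd1 was at 535 ± 25.5 and 605 ± 161 CPM (unadjusted p = 0.331). The 5 sex-linked genes held 0 calls by these tools and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.85), each group having 1 library with the female pattern.

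Of the 23 lists tested, 9 were called with the preset correlation and 0 with an estimated correlation. Other groupings of the same 6 libraries gave up to 10 list calls with the preset correlation. The median, mean and test of a list differed in sign for the hedgehog list (median 0.43, mean -0.21, test down), limb mesenchyme (0.27, -0.30, up), muscle and somite (0.02, 0.26, down), cell cycle (0.01, -0.01, down) and sex-linked genes (0.08, 0.04, down).

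**Figure D3:**
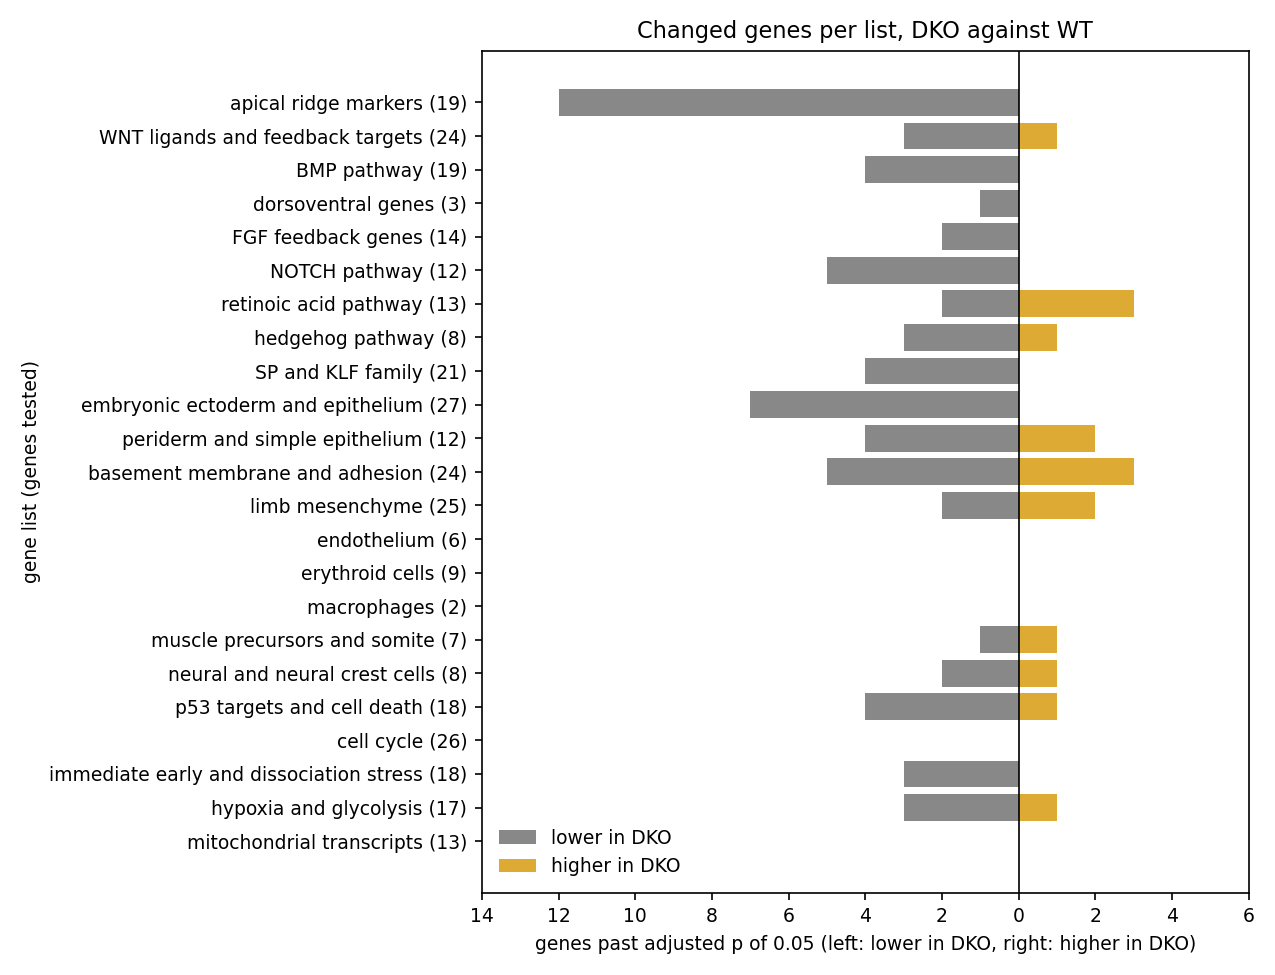
The gene lists fixed before the data were examined, except the sex-linked list, are on the y axis (genes tested in brackets). Bars count the genes past an adjusted p of 0.05 in edgeR (x axis), to the left those lower and to the right those higher in DKO. The ridge list has 12 genes lower and 0 higher of 19; the cell cycle, mitochondrial, endothelial, erythroid and macrophage lists have 0 in either direction.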

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

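The sex covariate and the removal of WT 32 and DKO 41 together were chosen only after the result was seen. No paired analysis was possible because the deposited columns carry no replicate numbers of the labels, so the replicate block was not run. Also not run were the alternatives for Sp6KO against WT at E10.5 (DESeq2, no filter, leaving out each library), whose libraries were not analysed here. Of the 10 splits of the 6 libraries into 3 and 3, the real one called 863 genes and the highest other 1, so 1 split had as many; the real one called 9 lists and the highest other 10 (DKO 17, DKO 40 and WT 32 against the rest), so 2 splits had as many. With 10 splits the share is never under 0.05. The 863 calls (325 higher, 538 lower) became 1737 (753, 984) with DESeq2, where 21101 genes were tested. On simulated data DESeq2 made 33.3% false calls, but only 100 genes were changed there at 2-fold and 100 at 4-fold. That share depends on the number of changed genes and does not carry over to the 1737 calls. The calls were 412 (116, 296) with no filter, where 29852 genes were tested, and 546 (200, 346) with the legacy dispersion. They were 318 (88, 230) against a 1.5-fold change and 377 (95, 282) without WT 32 and DKO 41, which leaves fewer samples. With voom 203 were higher. Without single libraries the counts ranged from 247 to 918 (53 to 332 higher, 194 to 592 lower); fewer samples lower the power of the test. The other settings (size factors of DESeq2, library totals, stricter filter, non-robust dispersion, sex covariate) gave within 1.5 times as many calls. The share of calls that were higher, 37.7%, lay between 21.5% and 44.1%. None of the calls that a setting also tested changed sign there (623 of the 863 were tested with the stricter filter and 862 without WT 32 and DKO 41). The first component held 57.2% of the variance with the stricter filter. Lists called numbered 0 with an estimated correlation, 2 with fry and 8 to 14 without single libraries. Sp6 ranged from -2.64 to -1.45 on the log2 scale without single libraries and passed without DKO 40 (-1.45). Among named genes and lists, 38 of 84 called genes kept their call without any 1 library. Those that changed direction were not called in the main test: with voom Xist (-4.02) and Eif2s3y (-0.28); without WT 32 and DKO 41, Alas2 (-1.22), Hba-a2 (-0.31) and the cell cycle list (adjusted p = 0.671); with library totals, the cell cycle list (0.941); with the stricter filter, the cell cycle list (0.806) and sex-linked list (0.92). Without single libraries, log2 fold changes ranged from -0.18 to 0.38 for Dlx5, -0.64 to 1.48 for Pax3, -0.05 to 0.33 for mt-Nd1, -0.04 to 0.66 for Lmx1b, -0.6 to 5.82 for Alas2, -1.07 to 0.13 for Uty, -12.71 to 4.95 for Xist, -0.83 to 0.42 for Ddx3y and -0.4 to 0.73 for Eif2s3y. Adjusted p-values ranged from 0.482 to 0.91 for the cell cycle list, 0.33 to 0.882 for the sex-linked, 0.0413 to 0.926 for the muscle and 0.0103 to 0.874 for the mitochondrial list. The cause of the other changes was not tested. Depth limits the lowest genes: 3 counts over the DKO group are 0.012 CPM. On simulated data edgeR missed some changes, recovering 46% at 2-fold. Those changed genes had a mean over 1 CPM, so this share does not measure the limit set by depth.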

Other observations

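Chosen only after the result was seen were the tests of wild-type ectoderm and of the targeted allele for Sp6, of genes near the targets, of the share of ectoderm and of a few libraries with other cells, of the imprinted genes, of the Hox paralogs and of the retinoid-induced genes. The genes Hoxb1, Hoxc5, Hoxc10, Hoxc13, Hoxb5, Hoxb9, Hoxd4, Hoxd9, Cdx1, Tgm2, Cyp26b1, Dlk1, Meg3, Rian, Scrn2, Gm11532 and Krt8 were also chosen after their values were seen.

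The Hox genes, which give cells their position along the body, were ordered by their place in the clusters. Of 22 tested genes of paralog groups 1 to 8, 21 had a positive log2 fold change and 9 were called higher (median 1.16). Among these were Hoxb1 (1.40 ± 0.641 to 7.19 ± 1.26 CPM, 5.16-fold, edgeR adjusted p = 0.00859, 0.0563 without WT 32) and Hoxc5 (64.9 ± 18.6 to 184 ± 8.86 CPM, 2.83-fold, adjusted p = 0.00357). Of 10 genes of groups 9 to 13, 3 were called lower and the median was -4.09, while 2 had a positive log2 fold change, Hoxb9 at 2.48 (4.39 without WT 32) and Hoxd9 at 0.62 (5.05), neither called. Those called lower included Hoxc10 (3.57 ± 1.15 to 0.253 ± 0.232 CPM; adjusted p = 0.0528 without WT 56; log2 fold change -3.86, and -4.59 and -3.23 without DKO 40 and DKO 41) and Hoxc13 (6.23 ± 3.54 to 0.309 ± 0.268 CPM; adjusted p between 0.0581 and 0.0722 without DKO 40, WT 32 or WT 56). Without WT 32, the WT library with the most Prrx1, the medians were 1.33 and -1.85, with 1 called higher (Hoxc5, edgeR adjusted p = 0.019) and 1 called lower (Hoxc10, 0.0185). DKO 40 and DKO 41 also held Prrx1 (23.3 and 12.8 CPM). Without DKO 40 or WT 56, 2 were called higher and 1 lower. A hypothesis is that the DKO ectoderm may have a more anterior Hox profile. Across genes, which are not independent replicates, the Spearman correlation of paralog number and log2 fold change was -0.64 with all libraries and -0.48 without WT 32 (Pearson -0.73 and -0.50). These are the genes whose values raised the hypothesis, so the correlation describes it and does not test it. Markers of mesenchyme in WT 32 and the other libraries keep open that part of this comes from other cells. Exons of Hoxc5 and Hoxc10 share 166 bases in the annotation.

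In the retinoic acid list, which was not called, 3 of 13 genes were higher and 2 lower. Besides Cyp26a1, the related degrading enzyme gene Cyp26b1 fell 5.29-fold (38.4 ± 4.05 to 7.25 ± 7.61 CPM, adjusted p = 0.0406; between 0.0918 and 0.144 without any 1 library but DKO 17, without which the log2 fold change went from -2.39 to -3.64), while Rarb and Aldh1a2 rose. A hypothesis is that genes induced by retinoic acid may rise as a group. A first list of 19 genes, some of which had already been seen to change, had 8 called higher and 2 lower (camera p = 5.77e-08, and 0.00486 with an estimated correlation). The 2 called lower, Cyp26a1 and Cyp26b1, are on this list as retinoid-induced genes, so their falls go against the hypothesis. They were taken out because they had raised the question. That left 17 genes (camera p = 3.51e-12, and 0.00458 with an estimated correlation), and these were then narrowed to 7. For these 7 the median log2 fold change was 1.30, with 2 called higher (Hoxb5 and Hoxd4) and 0 lower. The camera p was 0.000191 with the preset and 0.0184 with an estimated correlation, and with single libraries left out the latter lay between 0.0268 and 0.0415. Without DKO 40, WT 32 or WT 56 neither Hoxb5 nor Hoxd4 was called (adjusted p between 0.0876 and 0.151), and Hoxd4 was also not called without DKO 41 or WT 53. The log2 fold change of Hoxd4 was 4.36, and 3.71 without WT 56; its WT counts were in WT 32 alone, and without that library it was at least 36.5-fold higher. Cdx1 was at 20.0 ± 7.21 and 113 ± 82.7 CPM (edgeR adjusted p = 0.133, and 0.00369 without DKO 41). Tgm2 did not rise with all libraries, at 0.491 ± 0.0590 and 0.455 ± 0.615 CPM, a log2 fold change of -0.03. It was at -2.27 without DKO 41 (edgeR adjusted p = 0.25), 0.56 without DKO 17 and 0.29 without DKO 40, so this low gene moved both ways and does not decide. These 7 hold 5 Hox genes, which belong to the pattern above, so the test does not decide the question, and no retinoic acid level was measured.

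A group of imprinted genes, which are expressed from 1 parental copy, was higher. Dlk1 rose 5.22-fold (21.3 ± 7.24 to 111 ± 34.9 CPM, adjusted p = 0.00344), its neighbours Meg3 and Rian 4.54-fold and 6.48-fold, and Peg10 7.77-fold. Whether imprinted genes may rise as a group was tested on 27 others, with a median log2 fold change of 0.26 and quartiles of -0.06 and 0.74. Of these, 3 were called higher (0 without DKO 40, WT 32 or WT 56, and 1 without WT 53) and 0 lower. The camera p was 0.00408 with the preset and 0.179 with an estimated correlation, so the question stays open.

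Sp6 counts remained in DKO at 46.4%, 4.86% and 26.8% of the WT mean in DKO 17, DKO 40 and DKO 41. Wild-type ectoderm in these libraries would bring Fgf8 in the same share, but Fgf8 reached 1.08%, 0.0208% and 0.0739%, at most 0.023 of the Sp6 share, and Fgf4 had 0 counts. This argues against tissue like that of the WT libraries, though not against ectoderm without ridge cells. Transcript from the targeted Sp6 allele may account for it, and cannot be told apart from other sources because the table holds gene totals and no exon counts. For the same reason the counts cannot check the Sp6 genotype of a library, which was taken from the labels and column names. DKO 17 also kept the most Sp8, at 16.2% of the WT mean, against 6.57% in DKO 40 and 7.74% in DKO 41. Reads of the antisense gene Gm11532 could add to Sp6: its own counts were at most 0.064 of those of Sp6 in a DKO library, but that bound says little, since this chemistry does not mark the strand and 3329 exon bases overlap.

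Scrn2, whose gene (chromosome 11, 97029938 to 97033958) lies 5.2 kb from Sp6, rose 4.76-fold, from 73.3 ± 8.81 to 349 ± 110 CPM (edgeR adjusted p = 0.00133). Its exons share 0 bases with those of Sp6 in the annotation, which argues against reads shared through annotated exons. Reads of transcripts outside this annotation cannot be excluded, because the step that wrote the counts is not given. An effect of the targeted regions on nearby genes could be the source: with Scrn2, which raised the question, left out after the first run, 6 of 67 genes within 1 Mb of either target were called, against 855 of 19033 elsewhere (odds ratio 2.09, 95% interval 0.737 to 4.84, Fisher's exact p = 0.126, adjusted p = 0.252 over 18 such tests). With Scrn2 kept in, as first planned, the odds ratio was 2.44 (Fisher's exact p = 0.0332, adjusted p = 0.0996). Within 5 Mb and without Scrn2, 22 of 235 were called (odds ratio 2.22, Fisher's exact p = 0.00122, adjusted p = 0.0078), but without the Hoxb cluster too it was 17 of 224 (p = 0.0329, adjusted p = 0.0996), and 1 of 56 within 1 Mb. Around Sp6 alone and without Scrn2, 5 of 58 genes within 1 Mb were called. Without the Hoxb cluster too it was 0 of 47 (odds ratio 0, 95% interval 0 to 1.74). Whether a regional effect is seen within 1 Mb of Sp6 thus turns on the Hoxb genes, which belong to another pattern above. These values leave a regional effect open, as they do a response of Scrn2 to the loss of Sp8 and Sp6.

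In the epithelial and NOTCH lists, 7 of 27 and 5 of 12 genes were called lower, with medians of -0.54 and -1.10 on the log2 scale (adjusted p = 0.401 for each list with an estimated correlation). A lower share of ectoderm in DKO as the whole cause would lower epithelial markers alike and raise those of other cells. But of 24 epithelial markers with a mean over 50 CPM, 6 were lower and 2 higher. These 2 were Krt19 (2.70-fold) and Krt8 (1.39-fold, edgeR adjusted p = 0.0315, and between 0.0503 and 0.163 without any 1 library but DKO 17). On the mesenchyme list Meis2 rose 2.07-fold while Pdgfra fell 8.69-fold, both whichever library was left out. These 2 genes cannot decide, since they did not follow Prrx1 across the WT libraries. Pdgfra was highest in WT 56 (94.5 CPM), where Prrx1 was at 0.412 CPM, and Meis2 was at 78.4 CPM there and 83.3 CPM in WT 32. Without WT 32 the mesenchyme list moved up (median 1.58, camera adjusted p = 1.94e-05), which goes with a lower share of ectoderm. A lower share as part of the cause stays open, since 22 markers gathered for this question had a median of -0.45 (quartiles -0.71 and -0.15; camera p = 7.58e-06, and 0.196 with an estimated correlation), with 4 lower and 2 higher, 8 and 1 without DKO 41, 2 and 2 without DKO 17, 3 and 1 without WT 53, and 0 and 1 without DKO 40, WT 32 or WT 56. A few libraries with other cells stay open too: without WT 32 and DKO 41 the medians were -0.65 and -1.46, but DKO 40 (Prrx1 at 23.3 CPM) and WT 53 (erythroid genes at 302 CPM in sum) remained, and leaving out all 4 keeps 1 library in each group. A change in the epithelium with the loss of Sp8 and Sp6 stays open and was not tested.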
